A study of Mus musculus with 7 samples.

How the data were processed

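Messenger RNA of mouse eye samples was sequenced after selection of polyadenylated RNA, in 7 libraries of 3 Agbl5 genotypes: 3 knockout, 2 heterozygous and 2 wildtype. Per the labels' protocols the libraries were made with a NEBNext Ultra kit, which does not mark the strand, so reads of genes that overlap on opposite strands could not be separated. The tissue label read eyeball, while the extraction protocol spoke of retinal tissue. Neither the age of the mice nor whether the replicates of a genotype came from separate animals was stated. Xist and Ddx3y levels set wildtype 2 apart from wildtype 1, and knockout 3 from knockout 1 and 2, so these came from animals of different sex. Between heterozygous 1 and 2 and between knockout 1 and 2 the spread that the p-values rest on may be technical.

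The deposited table gave FPKM (fragments scaled by gene length and by library size) for 54532 genes, 1 column per library, as computed by the authors. Per the submitters' processing notes the tools were TopHat2 2.0.9, Bowtie2 2.0.6, HTSeq and DESeq, with the mouse builds mm10 and GRCm38; their order, their settings and the annotation release were not stated. Gene positions and exon lengths were taken from GENCODE mouse release M21, in which 54409 of the gene identifiers were found. With those lengths, 96.8% of the values above 0 were whole multiples of 1 step per library within a tolerance of 0.01, so whole reads could be recovered for 32117 genes in every library. Their sums ran from 12247365 to 14346825 reads per library. At this depth a single read on a gene of 1 kilobase stood for 0.0663 to 0.0766 FPKM. Checked on the values, the library size behind each deposited column stood in a fixed ratio to a median-of-ratios size factor in all 7 libraries, so the columns were already scaled by that method. A further median-of-ratios scaling, planned as an alternative, multiplied every library by 1 factor and moved nothing.

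FPKM were analysed as log2(FPKM + 1), on which fold changes understate those of genes at low levels. Genes with a mean of at least 1 FPKM over the 7 libraries were tested, 15472 in all. Differences were tested with limma 3.58.1 in R 4.3.3, by linear models with empirical Bayes moderation and a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. A fit with 3 genotypes, with 4 residual degrees of freedom, gave knockout against wildtype, knockout against heterozygous and heterozygous against wildtype. A fit with 2 groups, with 5 residual degrees of freedom, gave knockout against all controls, that is the heterozygous and wildtype libraries together. Values are means with their SD over libraries, and log2 fold changes carry their SE from limma. The all controls comparison uses the knockout libraries of the other comparisons and is not independent of them.

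In all, 29 gene lists, 14 of cell types and 15 of pathways, were written before the data were examined, as were the comparisons, the threshold and the rule for naming genes. Lists were tested with camera of limma, with a preset correlation of 0.01 between genes, with Agbl5 left out and at least 4 tested members. This left 27 lists, since the cornea and conjunctiva list and the skeletal muscle list had too few tested members. Each list was also tested with a correlation estimated from the libraries and with fry, which asks whether the members of a list move one way without comparing them with other genes. A count adjusted over the list alone was corrected for the members of that list only. The rule named Agbl5, then up to 12 genes with the largest rise and up to 12 with the largest fall among called genes whose groups did not overlap. It added up to 4 members with the smallest p of each list, and some genes whatever their value, among them Opn1sw, Opn1mw, Gfap and Aif1. Where fewer than 5 genes passed, the 6 named genes with the smallest p were given as not passing. Predicted genes and clone names were counted and not named. Other members of a list are named where they make up its count of called genes.

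The test was tried on simulated data of the same group sizes with 14558 genes. For knockout against wildtype it called 23.9% of 67 genes changed by 1.5-fold, 57.4% of 68 changed by 2-fold and 84.6% of 52 changed by 4-fold, with 6 false calls. For knockout against all controls the shares were 50.7%, 75% and 94.2%, with 10 false calls. A simulated list of 20 changed genes was found by the 3 list tests. Of 27 unchanged lists, camera called 0 in either comparison with either correlation, and fry called 1 for knockout against wildtype and 3 for knockout against all controls. Each simulated gene was drawn independently. In the real libraries the estimated correlation within a list was, for knockout against wildtype, 0.403 for gliosis and 0.939 for lens. The simulation therefore cannot show how the list tests fare where members move together.

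Other settings chosen before the data were examined were a pseudocount of 0.1, no filter and a filter at 5 FPKM, quantile normalization, rescaling of each column to a common sum (TPM), and the same rescaling without lens, cornea, muscle, red blood cell and mitochondrially encoded genes. Both rescalings multiply each library by 1 factor, which shifts all genes together. They also enlarge the values while the pseudocount stays at 1, so folds of genes at low levels grew on those scales. Agbl5, for example, went from -2.03 to -2.58 on the TPM scale against wildtype, where all tested genes shifted by a median of -0.16. Folds and list medians on those scales therefore differ from the deposited ones by both effects. Also chosen then were limma without the trend, array quality weights, the replicate number as a block, fits with 2 genotypes only, a contrast within the 3-genotype fit, and leaving out each library in turn. Settings chosen after seeing the data were the lens level, the Y-linked level or both as covariates, leaving out the 2 libraries rich in lens transcripts, leaving out gene models under 200 bases, and voom of limma on the recovered whole reads for 14788 genes. The alternatives for the list tests of knockout against heterozygous were also added after seeing the data. Where an alternative left a genotype with 1 library, that library was assumed to vary like the other groups. Count models were not run on the FPKM, which are not counts.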

Results

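Gene expression was measured by RNA sequencing in mouse eye samples with and without Agbl5, which encodes CCP5, an enzyme that removes glutamate branches from tubulin. The series asked what the gene does in photoreceptors. There were 3 knockout, 2 heterozygous and 2 wildtype libraries, with 12247365 to 14346825 recovered reads each. The series description spoke of wildtype and knockout mice, and the labels added the heterozygous libraries.

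Agbl5 transcript was lowest in knockout libraries and fell there against both other genotypes. Agbl5 (ENSMUSG00000029165, chromosome 5, 30888694 to 30906965 on the plus strand of GRCm38, 16 merged exons over 7053 bases) stood at 9.23 ± 0.935 FPKM in wildtype (SD, n = 2), 4.78 ± 0.805 in heterozygous (n = 2) and 1.51 ± 0.233 in knockout libraries (n = 3). The knockout level was lower than wildtype by a log2 change of -2.03 ± 0.13 (SE; limma, adjusted p = 0.00406) and lower than heterozygous by -1.20 ± 0.13 (adjusted p = 0.0239). The heterozygous level differed from wildtype by -0.83 ± 0.14 and did not pass the test over all genes (adjusted p = 0.974), although the libraries of the 2 genotypes did not overlap. Knockout libraries still held 122 to 172 reads on the gene, against 911 to 1020 in wildtype. Exons of Ost4 overlap the gene, and the libraries carried no strand, so it was not possible to assign the remaining reads. The call against wildtype was lost without wildtype 1 (-1.94, adjusted p = 0.0768), without wildtype 2 (-2.12, adjusted p = 0.0728), without both lens-rich libraries (-2.04, adjusted p = 0.0518) and with the replicate number as a block (-1.96, adjusted p = 0.0841). The call against heterozygous was lost in every run with 1 library left out, with log2 changes from -1.34 to -1.06, and held in 7 of its 22 alternatives.

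**Figure D1:**
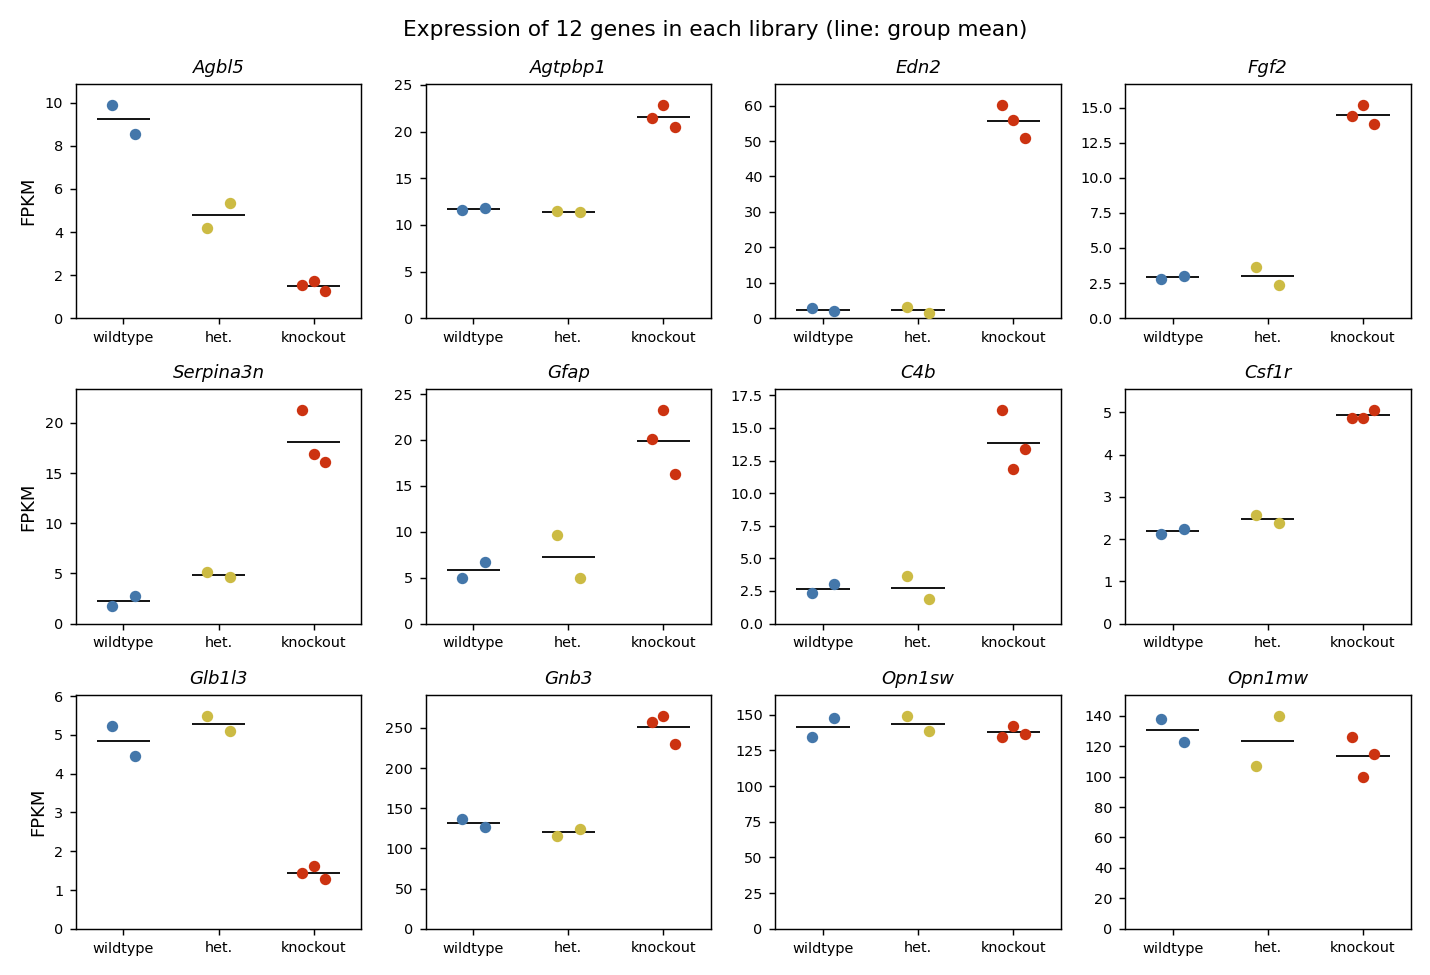
Expression in FPKM (vertical axes) of 12 genes in each library, grouped as wildtype (n = 2), heterozygous (n = 2) and knockout (n = 3); dots are libraries and lines are group means. Agbl5 falls from 9.23 to 1.51 FPKM between wildtype and knockout, and Edn2 rises from 2.45 to 55.6 FPKM.

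Lens transcripts and sex-linked transcripts set single libraries apart, and neither followed genotype. Cryaa, the gene of a major lens crystallin, was at 1733 FPKM in heterozygous 1 and 2541 FPKM in knockout 1, and between 1.11 and 12.3 FPKM in the other 5 libraries. The mean log2 level of the lens list was 6.21 and 6.17 in those 2 libraries and between 0.45 and 1.59 elsewhere. Xist, the RNA of the inactive X chromosome, was at 181 FPKM in wildtype 2 and 158 FPKM in knockout 3, and Ddx3y, on the Y chromosome, was listed at 0 in both. The first principal component held 35.3% of the variance and the second 20.5%. A single short RNA gene model, Gm23935, took from 2.16% to 17.2% of the FPKM sum of a library.

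**Figure D2:**
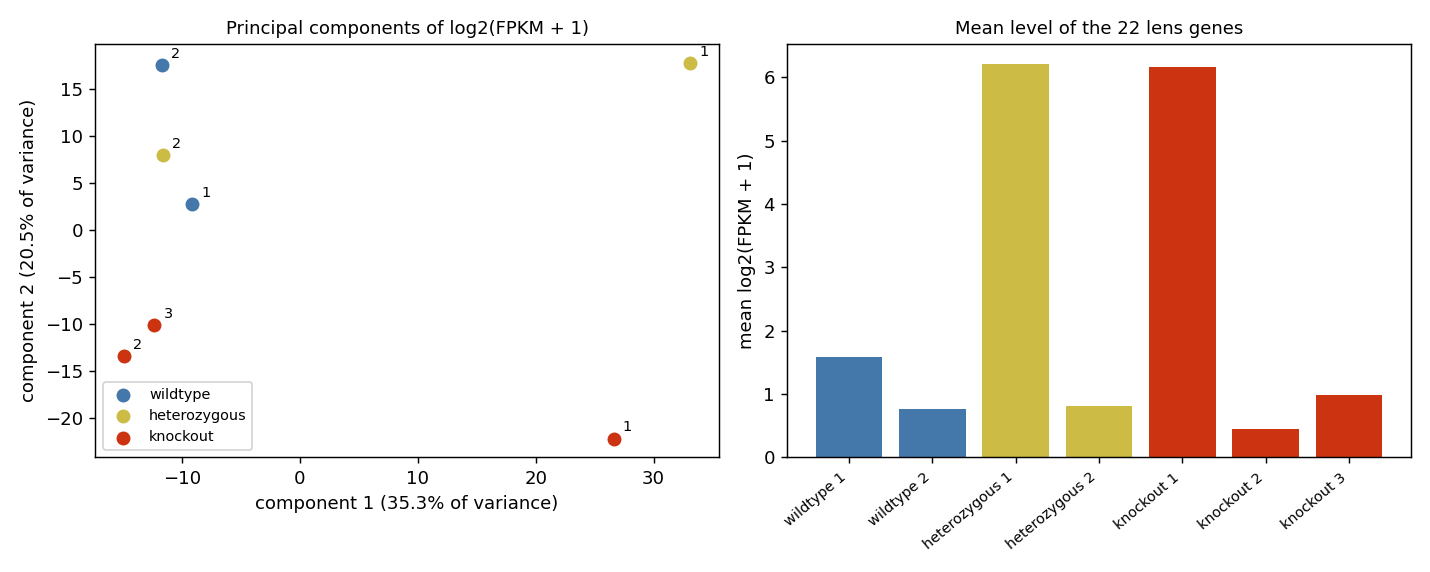
Principal components of the 7 libraries on log2(FPKM + 1) and the mean log2 level of the lens list in each library (bars, from 0); points and bars are libraries coloured by genotype, and the numbers at the points are replicates. Heterozygous 1 and knockout 1 have lens levels of 6.21 and 6.17, and the other 5 libraries lie between 0.45 and 1.59.

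Knockout was compared with wildtype to ask which transcripts differ when Agbl5 is lost. Edn2, which encodes the vasoactive peptide endothelin 2, had the largest rise, from 2.45 ± 0.769 FPKM in wildtype (n = 2) to 55.6 ± 4.61 in knockout (n = 3), a log2 change of 4.05 ± 0.23 (SE; adjusted p = 0.00406). Serpina3n, a serine protease inhibitor of reactive glia, rose from 2.23 ± 0.713 to 18.1 ± 2.77 FPKM (2.57 ± 0.17, adjusted p = 0.00406). Fgf2, the gene of basic fibroblast growth factor, rose from 2.91 ± 0.126 to 14.5 ± 0.683 FPKM (1.98 ± 0.14, adjusted p = 0.00457). Stat3, a transcription factor of cytokine signalling, rose from 7.58 ± 0.0940 to 18.4 ± 1.43 FPKM (1.17 ± 0.08, adjusted p = 0.00406). Glb1l3, a gene of the beta-galactosidase family, had the largest fall after Agbl5, from 4.84 ± 0.541 to 1.45 ± 0.170 FPKM (-1.25 ± 0.11, adjusted p = 0.00888).

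Lad1, which encodes the anchoring filament protein ladinin, rose by 2.28 in log2 from a wildtype level of 0.522 FPKM, and Tnnt2, the gene of cardiac troponin T, by 1.68 from 0.413 FPKM. The protease inhibitor gene A2m rose by 1.89, the stress-inducible gene Gadd45b by 1.60, Pcolce, which encodes an enhancer of procollagen processing, by 1.52, Fgf2os by 1.51 and Lrrc2 by 1.48. Of their alternatives Serpina3n was called in 21 of 23, Fgf2, Fgf2os and Lrrc2 in 20 of 23 each, Stat3 in 19 of 23, A2m in 18 of 22 and Tnnt2 and Glb1l3 in 16 of 22 each. Lad1 was called in 15 of 22, Pcolce in 15 of 23 and Gadd45b in 13 of 23, with adjusted p up to 0.224. Mir300 also passed (adjusted p = 0.0357), but its model of 79 bases held 2 reads in each knockout library and 0 in both wildtype libraries. No fold is given, and the call held in 9 of its 21 alternatives. The other named falls were smaller: Cars, the cysteinyl tRNA synthetase gene, fell by 0.65 on the log2 scale, Spc25, a kinetochore component, by 0.59, Rabgef1, an exchange factor for Rab5, by 0.54, and Fam3c, a secreted cytokine-like protein, by 0.52. Their calls were lost on the TPM scale (adjusted p = 0.0575, 0.102, 0.0628 and 0.0703), where they stood at -0.85, -0.77, -0.70 and -0.69 and all tested genes shifted by a median of -0.16. Of 23 alternatives Cars was called in 14, Spc25 in 6, Rabgef1 in 12 and Fam3c in 8, with adjusted p up to 0.413. Exons of Nudt6 and a predicted gene overlap Fgf2, those of Stat5a overlap Stat3, those of Fbxo24 overlap Pcolce and those of a predicted gene overlap Cars, so the values of these genes are uncertain without strand. In all, limma called 50 of 15472 genes, 41 higher and 9 lower, of which 38 were protein coding. The 2 genotypes did not overlap in any of the 50, and they did not overlap in 28.2% of all tested genes, where chance gives 20%. The count was 5 without wildtype 1 and 5 without wildtype 2, 19, 21 and 32 without knockout 1, 2 and 3, and 3 without both lens-rich libraries (Edn2, Fgf2 and Lrrc2). Edn2 stayed called in all of these. It was 28 on the TPM scale, where the median of all tested genes shifted by -0.16, 31 without the non-retinal and mitochondrial genes, where it shifted by -0.17, 33 with the lens level and 33 with the Y-linked level as a covariate, 22 with both, and 77 with voom.

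Genes of the gliosis, complement and microglia lists were higher in knockout as groups. The libraries hold whole tissue, so the values do not show in which cells a gene rose. The gliosis list had a median log2 change of 1.09 over 16 members, of which 6 rose (Edn2, Serpina3n, Fgf2, Stat3, A2m and the transcription factor gene Cebpd) and 12 rose when adjusted over the list alone (camera, adjusted p = 1.27e-22; adjusted p = 0.101 with an estimated correlation). Gfap, the intermediate filament gene of astrocytes and reactive Mueller glia, stood at 5.85 ± 1.26 FPKM in wildtype (n = 2) and 19.9 ± 3.44 in knockout (n = 3) without passing (1.61 ± 0.27, adjusted p = 0.126). The complement list had a median of 0.93 over 6 members, of which C4b (2.01 ± 0.23), C1qb (0.86 ± 0.09) and C1qc (0.76 ± 0.09) rose, and 6 rose when adjusted over the list alone (camera, adjusted p = 3.87e-13; adjusted p = 0.0513 with an estimated correlation). Serping1, an inhibitor of the first complement component, narrowly missed the threshold (1.03 ± 0.14, adjusted p = 0.0515). The microglia and macrophage list had a median of 0.55 over 14 members, of which Csf1r (0.90 ± 0.08), C1qb and C1qc rose, and 8 rose when adjusted over the list alone (camera, adjusted p = 5.24e-15; adjusted p = 0.0264 with an estimated correlation). C1qa, C1qb and C1qc were members of both lists. Csf1r, the receptor gene of a macrophage growth factor, has exons overlapped by Hmgxb3. Aif1, another microglial gene, was below the filter, at 0.0866 and 0.312 FPKM in wildtype and 0.382 to 0.833 FPKM in knockout libraries. The interferon and antigen presentation list had a median of 0.38 over 16 members, of which the class I histocompatibility gene H2-K1 rose (0.70 ± 0.07), and 8 rose when adjusted over the list alone (camera, adjusted p = 4.15e-12; adjusted p = 0.0351 with an estimated correlation). C4b, Serpina3n and H2-K1 have close paralogs that can share reads. On the TPM scale the calls of Csf1r (adjusted p = 0.0647), C1qb (0.0791), C1qc (0.126) and H2-K1 (0.292) were lost, with log2 changes there of 0.93, 0.79, 0.76 and 0.58. Over all their alternatives the largest adjusted p of these 4 genes was 0.292. C4b was called in 14 of 23 alternatives (adjusted p up to 0.266), C1qb in 12 of 23, Csf1r in 11 of 21, H2-K1 in 10 of 22 and C1qc in 9 of 22.

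Of the rod and cone genes on the lists, Gnb3 alone passed between knockout and wildtype. The cone opsin genes were at 141 ± 9.43 FPKM in wildtype (n = 2) and 138 ± 4.01 in knockout (n = 3) for Opn1sw (-0.03 ± 0.07, adjusted p = 0.938), and at 130.2 ± 10.9 and 113 ± 13.1 FPKM for Opn1mw (-0.20 ± 0.14, adjusted p = 0.812). The rod list fell, with a median of -0.08 on the deposited scale and -0.24 on the TPM scale over 30 members and no member called, also when adjusted over the list alone (camera, adjusted p = 0.0108; adjusted p = 0.462 with an estimated correlation). Among rod genes Sag, which encodes arrestin, was at 364 FPKM in wildtype and 478 FPKM in knockout without passing (adjusted p = 0.29). The cone list did not pass, with a median of -0.08 over 17 members (adjusted p = 0.0703). Of its members Gnb3, the beta subunit gene of cone transducin, rose from 132 ± 7.66 to 251 ± 18.2 FPKM (0.92 ± 0.08, adjusted p = 0.0129), and Arr3, the cone arrestin gene, was at 169 FPKM in wildtype and 122 FPKM in knockout without passing (adjusted p = 0.543). The Gnb3 call was lost on the TPM scale (0.76, adjusted p = 0.0628; 0.183 at most over its alternatives).

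Among genes that act on tubulin, Agtpbp1 rose, which encodes the deglutamylase CCP1, a relative of CCP5. It went from 11.7 ± 0.144 FPKM in wildtype (n = 2) to 21.6 ± 1.19 in knockout (n = 3; 0.83 ± 0.07, adjusted p = 0.00624). It was the only called gene of the 12 tested glutamylation and deglutamylation enzymes, also when adjusted over the list alone. That list did not pass (camera, adjusted p = 0.463), and its median of -0.04 and its mean of 0.08 differed in sign, with the test pointing up. With fry, which does not compare members with other genes, the list passed upward (adjusted p = 0.00389; 0.0342 against heterozygous and 0.0279 against all controls). The tubulin isotype list rose on the deposited scale, with a median of 0.09 over 14 members, 0 called and 2 higher when adjusted over the list alone (camera, adjusted p = 0.0136; adjusted p = 0.462 with an estimated correlation). The call was lost on the TPM scale (adjusted p = 0.0811) and without the non-retinal and mitochondrial genes (adjusted p = 0.0876). The list medians on those 2 scales, -0.07 and -0.08, lay above the medians of all tested genes, -0.16 and -0.17. The change of sign thus came with the shift of all genes. The call was also lost without knockout 2 (median 0.06, camera, adjusted p = 0.0869) and with the lens level as a covariate (0.08, adjusted p = 0.0577). Further losses came without wildtype 2 (median 0.09) and without both lens-rich libraries (0.09). Tubb2b stood at 5.71 and 9.37 FPKM in wildtype and knockout without passing (adjusted p = 0.158). Transport in the cilium was represented by 3 lists and none passed: intraflagellar transport (32 members, median -0.02, adjusted p = 0.65), the BBSome, transition zone and connecting cilium (34 members, median -0.04, adjusted p = 0.192) and outer segment protein trafficking (20 members, median and mean 0.00 with the test pointing down, adjusted p = 0.966). Limma called 0 members of these lists, with 1, 2 and 2 at an unadjusted p under 0.05, and voom called 0, 1 and 0. Adjusted over the list alone 1 member of the BBSome list was higher and no other was called. Arl6, a small GTPase that recruits the BBSome, was at 46.1 and 67.7 FPKM in wildtype and knockout without passing (adjusted p = 0.155). The Agtpbp1 call was lost on the TPM scale (0.71, adjusted p = 0.102; 0.113 at most over its alternatives).

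Among the other cell types, amacrine cell genes fell by a median of 0.14 (12 members, adjusted p = 0.0108) and retinal ganglion cell genes by a median of 0.13 (12 members, adjusted p = 0.00606), both with adjusted p = 0.469 with an estimated correlation and no member called. On the TPM scale their medians were -0.30 and -0.30. Pigment epithelium and melanocyte genes rose by a median of 0.44 (13 members, 0 called, adjusted p = 0.0072; adjusted p = 0.595 with an estimated correlation), with Ttr, the transthyretin gene, at 30.0 ± 12.2 and 71.5 ± 18.6 FPKM in wildtype and knockout. The genotypes overlapped in the mean log2 level of that list, at 1.97 and 3.11 in wildtype 1 and 2 and at 3.68, 2.19 and 3.08 in knockout 1, 2 and 3. Its call was lost without wildtype 1 (median 0.00, adjusted p = 0.555) and without knockout 1 (0.01, adjusted p = 0.195). Without wildtype 1 the calls of the rod (median -0.04), ganglion cell (-0.11), amacrine cell (-0.11) and red blood cell lists (-0.24) were lost as well. Red blood cell genes fell by a median of 0.52 (4 globin members, 0 called, adjusted p = 0.00422; adjusted p = 0.462 with an estimated correlation). Mitochondrially encoded genes fell by a median of 0.18 (13 members, 0 called, adjusted p = 0.000374; adjusted p = 0.457 with an estimated correlation; median -0.35 on the TPM scale). On that scale the red blood cell median was -0.79. The lens list did not pass although its median was 1.43 (22 members, adjusted p = 0.0702), with its high levels in knockout 1 alone among these 5 libraries. Bipolar cell genes (median -0.05, adjusted p = 0.124), horizontal cell genes (-0.10, adjusted p = 0.124), vascular genes (-0.07, adjusted p = 0.546) and Y-linked genes (0.54, adjusted p = 0.567) did not pass. Mueller glia identity genes did not pass either (adjusted p = 0.351), with a median of -0.00 and a mean of 0.15, the test pointing up. Of them Crym, a thyroid hormone binding protein, rose (0.92 ± 0.11, adjusted p = 0.0369, lost on the TPM scale with 0.163; 0.383 at most over its alternatives), and 2 rose when adjusted over the list alone. The lists of cell death (median 0.11, adjusted p = 0.138), the unfolded protein response (median 0.03, mean -0.03 with the test pointing down, adjusted p = 0.464), glycolysis (median -0.00, mean 0.01 with the test pointing up, adjusted p = 0.815), immediate early genes (median 0.01, adjusted p = 0.65) and the circadian clock (median -0.06, adjusted p = 0.0856) did not pass with camera. With fry the circadian clock list passed downward (adjusted p = 0.0191). On the TPM scale the medians were -0.03 for cell death, -0.13 for the unfolded protein response and -0.15 for immediate early genes. Adjusted over the list alone, 1 gene of the unfolded protein response was lower, 1 immediate early gene was higher and no member of the 3 other lists was called. In all, 11 of 27 lists passed with the preset correlation, 2 with an estimated correlation and 6 with fry.

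**Figure D3:**
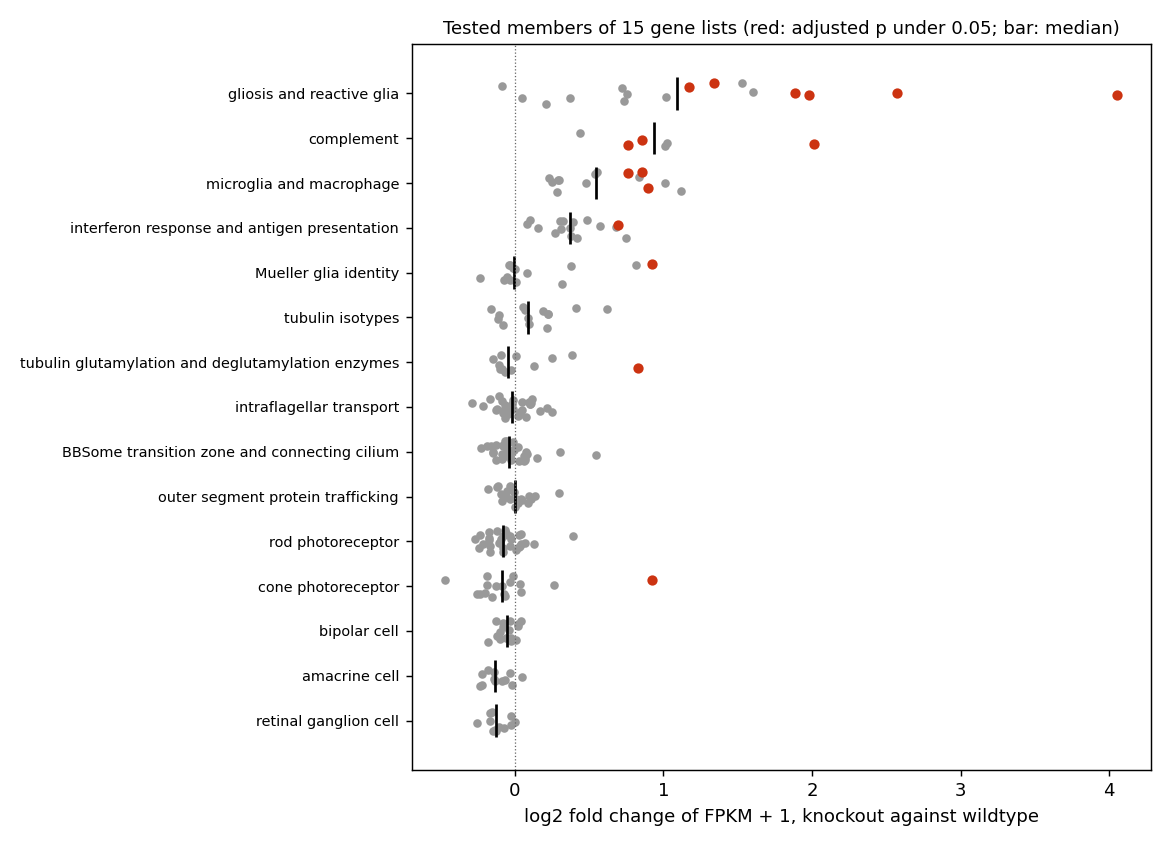
Log2 fold change of knockout against wildtype (horizontal axis) for the tested members of 15 gene lists; dots are genes, red dots passed at an adjusted p under 0.05, and bars are list medians. Medians are 1.09 for gliosis, 0.93 for complement and 0.55 for microglia, and -0.08 for rod genes.

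Knockout was compared with heterozygous to ask what the loss of the remaining allele adds. Edn2 rose from 2.28 ± 1.15 FPKM in heterozygous (n = 2) to 55.6 ± 4.61 in knockout (n = 3; 4.15 ± 0.23, adjusted p = 0.00491). Cebpd rose from 1.76 ± 0.112 to 9.07 ± 1.88 FPKM (1.85 ± 0.16, adjusted p = 0.00959). Antxr2, an anthrax toxin receptor gene, rose from 1.41 ± 0.124 to 5.18 ± 0.253 FPKM (1.36 ± 0.09, adjusted p = 0.00491), and Rfx2, a transcription factor of ciliated cells, from 1.59 ± 0.231 to 5.62 ± 0.458 FPKM (1.36 ± 0.11, adjusted p = 0.00745). Crxos, which lies opposite the photoreceptor transcription factor gene Crx, fell from 26.5 ± 2.32 to 16.7 ± 0.765 FPKM (-0.63 ± 0.08, adjusted p = 0.0349). Lad1 (2.45), C4b (2.01), Fgf2 (1.97), Tnnt2 (1.79), Gadd45b (1.72), Serpina3n (1.69), Fgf2os (1.51) and Lrrc2 (1.38) rose, and Glb1l3 (-1.36) and Rabgef1 (-0.61) fell. Csf1r (0.77), C1qb (0.92), C1qc (1.01), Gnb3 (1.06), Crym (0.97), Agtpbp1 (0.86), H2-K1 (0.58) and H2-D1 (0.51) rose as well. On the TPM scale the calls of Crxos and Rabgef1 (adjusted p = 0.0574 each), Agtpbp1 (0.0539), Crym (0.0864), Csf1r (0.0958), H2-K1 (0.343) and H2-D1 (0.388) were lost. In that order their log2 changes there were -0.74, -0.70, 0.82, 0.93, 0.84, 0.53 and 0.45. Over all alternatives the largest adjusted p of these genes was 0.388. H2-K1 was called in 4 of 22 alternatives, Csf1r in 5 of 21, Crxos in 5 of 23, Crym in 6 of 23 and H2-D1 in 6 of 23. C4b and C1qb were called in 12 of 23 each, Serpina3n in 14 of 23, Gadd45b and Rabgef1 in 15 of 23 each and C1qc in 15 of 22. Limma called 49 genes, 42 higher and 7 lower. The 2 genotypes did not overlap in any of them, nor in 29.8% of all tested genes, where chance gives 20%. The count was 14 without heterozygous 1, 31 without wildtype 1 and 31 without wildtype 2, 30, 22 and 25 without knockout 1, 2 and 3, and 31 with the 2 genotypes alone in the fit. Without both lens-rich libraries limma called 0 genes, with 1313 at an unadjusted p under 0.05. With the lens and Y-linked covariates together it called 22, and voom on all libraries called 76.

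The gliosis list rose in knockout against heterozygous by a median of 1.07, with 6 members called and 11 adjusted over the list alone (camera, adjusted p = 2.49e-12; adjusted p = 0.266 with an estimated correlation). The complement list rose by 0.93, with C4b, C1qb and C1qc called and 5 adjusted over the list alone (adjusted p = 2.25e-09; adjusted p = 0.139 with an estimated correlation). The microglia list rose by 0.54, with Csf1r, C1qb and C1qc called and 9 adjusted over the list alone (adjusted p = 4.57e-09; adjusted p = 0.0732 with an estimated correlation). The interferon list rose by 0.20, with H2-K1 and H2-D1 called and 3 adjusted over the list alone (adjusted p = 0.000299; adjusted p = 0.18 with an estimated correlation). Immediate early genes (median 0.24, 2 adjusted over the list alone, adjusted p = 0.000299; adjusted p = 0.379 with an estimated correlation) and glycolysis genes (median 0.12, 1 adjusted over the list alone, adjusted p = 0.00175; adjusted p = 0.707 with an estimated correlation) rose with no member called. The heterozygous libraries stood low in the first of these lists, at mean log2 levels of 3.93 and 3.98, against 4.23 and 4.35 in wildtype and 4.21 to 4.46 in knockout libraries. Between knockout and wildtype neither list passed, with medians of 0.01 and -0.00, so the rises cannot be put down to the remaining allele alone. Mitochondrially encoded genes fell by a median of 0.27 with no member called (adjusted p = 0.00931; adjusted p = 0.559 with an estimated correlation). The glycolysis call was lost without heterozygous 1 (median 0.07, adjusted p = 0.117), without both lens-rich libraries (0.07, adjusted p = 0.163), with quantile normalization (0.05, adjusted p = 0.0925) and with fry (adjusted p = 0.301), and its median was 0.03 on the TPM scale. The mitochondrial call was lost without heterozygous 2 (median -0.31, adjusted p = 0.0528), without a filter (adjusted p = 0.33), with quantile normalization (-0.12, adjusted p = 0.37) and with fry (adjusted p = 0.169). The call of the immediate early genes was lost with fry as well (adjusted p = 0.0742). Of the 27 lists 7 passed with the preset correlation, 0 with an estimated correlation and 5 with fry.

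Heterozygous was compared with wildtype to ask whether 1 mutant allele leaves a mark. No gene passed: limma called 0 of 15472 genes, with 619 at an unadjusted p under 0.05 (4%), while voom called 0, limma without a filter 19 and limma with the 2 genotypes alone 1. The named genes with the smallest p were Mir7027, a model of 72 bases with 10 reads in each wildtype and 3 in each heterozygous library (9.35 ± 0.202 FPKM in wildtype and 3.07 ± 0.171 in heterozygous, n = 2 each, adjusted p = 0.348), Mir300, Cars (-0.48 ± 0.08 in log2), Mthfd2, an enzyme of mitochondrial folate metabolism (5.86 ± 0.665 and 2.75 ± 0.727 FPKM), Agbl5 and Apip, an enzyme of methionine salvage (11.7 ± 0.112 and 8.77 ± 0.281 FPKM), all but the first with adjusted p = 0.974. Serpina3n stood at 2.23 ± 0.713 and 4.88 ± 0.333 FPKM without passing. Agbl5 itself differed by -0.83 in log2 without a call, and the simulation did not cover this comparison. The count of 0 genes therefore does not show that 1 mutant allele has no effect. The 2 genotypes did not overlap in 30% of the tested genes, where chance gives 33.3%. With the preset correlation 10 lists passed, each with adjusted p = 0.559 with an estimated correlation, and with no member called. Adjusted over the list alone 1 gliosis gene was higher and 1 immediate early gene lower. Upward they were lens (median 2.42), Y-linked genes (1.74), pigment epithelium and melanocyte (0.45), interferon (0.19) and gliosis (0.13). Downward they were red blood cell (-0.47), immediate early genes (-0.27), glycolysis (-0.16), the unfolded protein response (-0.10) and outer segment protein trafficking (-0.10). The lens median turned to -0.26 without heterozygous 1, and the pigment epithelium call was lost without wildtype 1 (0.08, adjusted p = 0.784). Without wildtype 1 the number of lists was 3 (lens, Y-linked and immediate early genes), and the medians were -0.19 for red blood cell, -0.06 for glycolysis and -0.05 for the unfolded protein response. Without heterozygous 1 it was also 3, of which immediate early genes alone had passed before, and the medians were -0.19 for red blood cell, -0.08 for glycolysis and 0.04 for gliosis. The Y-linked genes were listed at or near 0 in wildtype 2, and without that library their call was lost (median 0.115).

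Knockout was compared with all control libraries to ask what separates the 2 states with more libraries per group. Edn2 rose from 2.37 ± 0.806 FPKM in controls (n = 4) to 55.6 ± 4.61 in knockout (n = 3; 4.10 ± 0.18, adjusted p = 0.000296). Gfap passed here, from 6.57 ± 2.20 to 19.9 ± 3.44 FPKM (1.49 ± 0.22, adjusted p = 0.0324; 0.0536 on the TPM scale and 0.159 at most over its alternatives), as did Bcl3, a regulator of NF-kappa-B, from 0.172 ± 0.0590 to 2.30 ± 0.783 FPKM (1.46 ± 0.18, adjusted p = 0.0147). Agtpbp1 rose from 11.5 ± 0.163 to 21.6 ± 1.19 FPKM (0.85 ± 0.05, adjusted p = 0.000445) and Gnb3 from 126 ± 8.88 to 251 ± 18.2 FPKM (0.99 ± 0.08, adjusted p = 0.0013), and both stayed called in each of their alternatives. Agbl5 itself fell by 1.61 on the log2 scale (adjusted p = 0.0429; 0.26 at most over its alternatives), with an SE of 0.25 where heterozygous and wildtype libraries formed 1 group. Lad1 (2.36), Serpina3n (2.13), C4b (2.01), Fgf2 (1.97), Tnnt2 (1.73), Gadd45b (1.66), A2m (1.60), Cebpd (1.59), Fgf2os (1.51) and Stat3 (1.19) rose. Glb1l3 (-1.31), the spindle gene Knstrn (-0.76), Rabgef1 (-0.57), Crxos (-0.56), Spc25 (-0.52), Fam3c (-0.45), Tnfaip3, an inhibitor of NF-kappa-B signalling (-0.35), Hist2h2be, a histone gene (-0.33), and Ranbp6 (-0.29) fell. Knstrn was called in 9 of 22 alternatives (adjusted p up to 0.246) and Crxos in 15 of 23 (up to 0.116). On the TPM scale Spc25 (-0.66, adjusted p = 0.0668), Fam3c (-0.58, 0.054), Tnfaip3 (-0.48, 0.0991), Hist2h2be (-0.48, 0.0914) and Ranbp6 (-0.43, 0.145) lost their calls, with all tested genes shifted by a median of -0.12. Tnfaip3 and Hist2h2be were called in 5 of 23 alternatives each and Ranbp6 in 6 of 23, with adjusted p up to 0.273. Serpina3n was called in 15 of 23, Gfap in 10 of 23, Bcl3 in 16 of 22, A2m in 18 of 22, Cebpd in 18 of 23, Fam3c in 14 of 23 and Spc25 in 13 of 23. Exons of predicted genes overlap Knstrn and Bcl3, and those of Spidr overlap Cebpd.

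The gliosis list rose against all controls by a median of 1.08, with 8 members called and 11 adjusted over the list alone (camera, adjusted p = 8.43e-17; adjusted p = 0.0823 with an estimated correlation). The microglia list rose by 0.58, with Csf1r, Ctss, C1qa, C1qb and C1qc called and 9 adjusted over the list alone (adjusted p = 4.34e-13; adjusted p = 0.0127 with an estimated correlation). The complement list rose by 0.90, with C4b, Serping1 and the 3 C1q genes called and 6 adjusted over the list alone (adjusted p = 5.13e-12; adjusted p = 0.0207 with an estimated correlation). The interferon list rose by 0.28, with H2-K1 and H2-D1 called, both lost on the TPM scale (adjusted p = 0.0953 and 0.255, the largest of their alternatives), and 5 adjusted over the list alone (adjusted p = 5.48e-08; adjusted p = 0.0718 with an estimated correlation). Mitochondrially encoded genes fell by a median of 0.23 (adjusted p = 0.000613; adjusted p = 0.284 with an estimated correlation; median -0.35 on the TPM scale). Rod genes fell by 0.06 (adjusted p = 0.0377), retinal ganglion cell genes by 0.06 (adjusted p = 0.0478), and tubulin isotypes (0.10, adjusted p = 0.0187) and immediate early genes (0.13, adjusted p = 0.0443) rose, each of these 4 lists with adjusted p = 0.601 with an estimated correlation. Each of these 4 calls was lost in at least 1 run with a library left out. Among those runs the median was -0.04 for rod genes without wildtype 1 and -0.04 for ganglion cell genes without heterozygous 1. It was 0.05 for tubulin isotypes without knockout 2 and 0.07 for immediate early genes without heterozygous 1. On the TPM scale the medians were -0.19 for rod genes, -0.19 for ganglion cell genes, whose call was lost (adjusted p = 0.0814), and 0.01 for immediate early genes. The tubulin isotype call was lost on the TPM scale (adjusted p = 0.0814) and without the non-retinal and mitochondrial genes (adjusted p = 0.104). Intraflagellar transport (median -0.04, adjusted p = 0.352) and the BBSome list (adjusted p = 0.318) did not pass, with Arl6 the only called member (0.51 ± 0.08, adjusted p = 0.0429; 0.226 on the TPM scale and 0.24 at most over its alternatives) and a predicted gene overlapping its exons. In all, limma called 95 genes, 72 higher and 23 lower, and 65 of them were protein coding. The groups did not overlap in any of the 95, nor in 13% of all tested genes, where chance gives 5.71%. The count was 63 without wildtype 1, 59 without wildtype 2, 60 without heterozygous 2, 47, 45 and 53 without knockout 1, 2 and 3, and 48 without both lens-rich libraries. It was 63 on the TPM scale, where the median of all tested genes shifted by -0.12, and 150 with voom.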

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

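The split counts and the test of genes near Agbl5 were planned, and the tests of lens tissue, of the share of rods and of blood were chosen only after the results were seen.

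Among the 4 control libraries, 2 of 27 lists and 9 of 124 genes had 1 library far from the other 3, by the gap of that library divided by the whole range; chance gives about 1 in 20. The lens list stood apart in heterozygous 1 (0.847), as did the lens crystallin genes Cryga (1), Cryge (0.932) and Crygf (0.858), whose paralogs can share reads. The Y-linked list stood apart in wildtype 2 (0.967), as did Uty (0.957), Kdm5d (0.969), Ddx3y (0.956) and Eif2s3y (0.931). In heterozygous 1 the bipolar cell gene Vsx1 (0.886) and the horizontal cell gene Lhx1 (0.886) stood apart from the other controls.

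Between knockout and all controls 95 genes were called. Of the 35 splits of the 7 libraries into 3 and 4, only 1, the real one, gave as many (95, the highest other 2). This argues against chance for the genes, but 1 in 35 is the smallest share these splits can give. The count also treats the libraries as separate animals, which was not stated. For the number of lists chance was not excluded: 7 of the 35 splits gave at least the 9 lists of the real one, and the highest other gave 12. That count took lists of any kind and direction, so it does not bear on the gliosis, complement or microglia lists taken alone. Lens levels were high in knockout 1 (6.17) and in the control heterozygous 1 (6.21). Genes that followed the lens level alone would therefore overlap between the groups, and none of the 95 did. Without the 2 lens-rich libraries 43 of the 95 genes stayed called. The median size of the 95 was 0.82 before and 0.81 after in log2. All 95 kept their sign, but this was fixed in advance, since their groups did not overlap. The kept calls and sizes rest on libraries that also picked the 95, so they are not separate evidence. The 52 other calls ended with fewer libraries, at a median size of 0.56 before and 0.55 after and a median SE of 0.08 and 0.09. Against alleles carried along with the mutation as the whole cause, 2 called genes (Zfyve28 and Gm26954) of 238 tested lay within 20 Mb of Agbl5, 2.1% of the called and 1.54% of the tested genes (two-sided Fisher exact p = 0.657); a difference in age, litter or housing between genotypes stays open, since the labels gave none.

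Microglia and complement genes were higher in knockout than in wildtype. A lower share of rods would raise the genes of every other cell type alike, but the median over 45 members of the bipolar, amacrine, horizontal and ganglion cell lists was -0.097 (quartiles -0.146 and -0.026), under the lower quartile of the microglia list (0.293). More blood in knockout than in wildtype tissue is argued against by the red blood cell list. That list was lower by -0.54 in log2 (-0.26 without wildtype 1, where it was not called), with every knockout library below every wildtype library. With an estimated correlation it did not pass (camera, adjusted p = 0.462). Against heterozygous it was level (mean -0.02, camera, adjusted p = 0.848), with heterozygous 1 at 2.58 and the knockout libraries at 2.70 to 2.91. The argument thus covers wildtype only. Since these data hold whole tissue, more microglia and a higher level per cell both stay open. The gliosis, complement and microglia lists were written before the data were examined, and their rise was tested as given above. That it is a microglial and glial response to the loss of Agbl5 stays a hypothesis. Neither that link nor the cells involved were tested.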

How the results depend on the processing

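Alternatives with lens or Y-linked levels, without lens-rich libraries, without short gene models and with voom, and all for the lists of knockout against heterozygous, were chosen only after the results were seen. Every named gene kept its direction wherever it had been called, in all alternatives run. Since the groups of every called gene did not overlap, runs with libraries left out could not have turned it. Edn2 stayed called against wildtype in all 23 of its alternatives (3.82 to 4.53). So did Stat3, Fgf2, C4b and Agtpbp1 against all controls. A further median-of-ratios scaling moved nothing, since the columns were already so scaled, and says nothing on stability. Leaving out 1 library gave 5 to 53 genes for knockout against wildtype, 14 to 40 against heterozygous, 45 to 90 against all controls and 0 to 3 for heterozygous against wildtype; fewer libraries leave fewer degrees of freedom. The lists called ran from 8 to 14, from 7 to 10 against heterozygous, from 7 to 10 against all controls and from 3 to 10 for heterozygous against wildtype, and Agbl5 from -2.12 to -1.94. Without both lens-rich libraries the counts were 3 against wildtype, 0 against heterozygous and 48 against all controls, with Agbl5 at -2.04, not called (adjusted p = 0.0518), and 3 lists for heterozygous against wildtype. The TPM scale gave 28 and 63 genes against wildtype and all controls. Leaving out non-retinal and mitochondrial genes gave 31 against wildtype, with the share of called genes that were higher at 71% in place of 82%. Both scales divide by sums that held Gm23935, which took 2.16% and 5.45% of the deposited sum in wildtype and 7.04% to 17.2% in knockout libraries. It thus lowered other genes more in knockout than in wildtype libraries. No rescaling without it was run, and its part in the lost calls was not tested. With the lens level as a covariate 33 genes were called against wildtype, with the Y-linked level 33, with both 22, and 22 against heterozygous; 5 lists passed for heterozygous against wildtype with the lens level and 5 with a filter at 5 FPKM. Voom gave 77 genes against wildtype, 76 against heterozygous and 150 against all controls; the cause was not tested. With 2 genotypes in the fit 31 genes were called between knockout and heterozygous and 1 between heterozygous and wildtype, where no filter gave 19. With an estimated correlation 2 lists passed against wildtype, 2 against all controls, 0 against heterozygous and 0 for heterozygous against wildtype; fry gave 6 against wildtype and 0 for heterozygous against wildtype.

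The lens list for heterozygous against wildtype turned from 2.42 to -0.256 without heterozygous 1 and without both lens-rich libraries (-0.256 to 5.28 over the runs with 1 library left out), to -0.11 with the lens level and to -0.121 with both covariates; its rise came from heterozygous 1. With the replicate number as a block the counts were 3 against wildtype, 0 against heterozygous (limma, with 1449 at an unadjusted p under 0.05) and 38 against all controls, with Agbl5 at -1.96 and no longer called (adjusted p = 0.0841). Correlations across genes between libraries of 1 number, after removing genotype means, ran from -0.02 to 0.43. The highest was between both lens-rich libraries, and heterozygous 2 with knockout 2 gave 0.27. In genotypes of 2 libraries the deviations mirror each other, so these correlations could not decide whether the numbers mark a pairing. Depth of 12247365 to 14346825 reads limits genes near the filter, where a few reads move a value.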

Other observations

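The test of a tRNA and amino acid gene list was chosen only after the result was seen.

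Cars, which charges tRNA with cysteine, and Mthfd2, an enzyme of folate metabolism, were lower in heterozygous than in wildtype libraries without passing, and Cars was called in knockout against wildtype. The hypothesis was that genes of tRNA charging and amino acid synthesis are lower as a set in both mutant genotypes. A list of 33 such genes without those seen first, 31 of them tested, was lower in heterozygous than in wildtype by a median of -0.10, with 23 members lower (camera with an estimated correlation, p = 0.0442). Against wildtype the knockout libraries gave a median of -0.06 with 19 members lower, and against heterozygous a median of -0.03. Adjusted over these 3 comparisons neither difference from wildtype passed (camera with an estimated correlation, adjusted p = 0.069 for both). The result is consistent with the hypothesis but weak, since no member was called and both comparisons share the same 2 wildtype libraries, which may themselves stand high.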
